A study of Mus musculus with 298 samples.

How the data were processed

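Single neurons of the mouse suprachiasmatic nucleus (SCN), the hypothalamic clock, were recorded by patch clamp in slices and their cytoplasm was drawn into the pipette for RNA sequencing. Per the labels' protocols, libraries were made with the Nextera XT kit, and several neurons could come from the same slice. Mice were kept in 12 h of light and 12 h of dark, and slices were prepared near ZT0 for the day cells and near ZT12 for the night cells, where ZT0 is lights on. Each deposited sample was 1 cell, with a label for time of day, for firing (active, silent or depolarized) and for cFOS (cFOS+ or cFOS-). How the cFOS label was assigned is not given in the sources used here.

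The authors deposited raw counts per gene for 22800 gene symbols in 298 cells. They also deposited a table of normalized values, a signal without a further unit, and its logarithm, which was not used. In all 298 columns the deposited normalized signal equalled the counts divided by 1 factor per cell, to a relative tolerance of 1e-06. The submitters' processing notes name STAR, DESeq2 and the genome build GRCm38.p4 without saying which step used which tool. Versions, the gene annotation, the counting tool and the use of strand are not given in the sources used here, so reads of overlapping genes or near-identical paralogs may be split between symbols. No molecular identifiers are mentioned, so the counts are reads. Intervals of CPM below cover the counting error of reads only, and intervals of shares treat cells as independent draws. Neither covers differences between animals or slices. Gene positions were taken from the GENCODE M21 annotation of GRCm38, which is not the annotation behind the counts.

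Total counts ran from 3187057 to 25535298 reads per cell, with a median of 6320667, and the medians of the 12 groups lay between 5186344.5 and 7845767.5. Detected genes ran from 2341 to 8420 per cell. All 298 columns had a sample, and no filter on cells was applied. No doublet caller was run, because each library came from 1 pipette; RNA of other cell types was followed through marker lists instead. Cells S70 and S71, both night silent but with opposite cFOS labels, had nearly identical profiles. Their correlation of log2 (CPM + 1) across genes was 0.9995, against 0.696 for the next of 44253 pairs. The chi-square of their counts was 4.55 per degree of freedom, above sampling noise, against at least 408.9 in 1190 other pairs of the same groups. They were averaged and counted as 1 cell without a cFOS label, leaving 297 distinct cells.

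The labels name no animal or slice for any cell. Cells are not replicates, so each group was treated as 1 sample: groups were not tested against each other, and no p-value, standard error or number of changed genes was computed. Dixon's limit for an extreme value was applied only among the 7 day depolarized cFOS- cells. Counts were summed over the cells of a group and given as CPM, counts scaled to the total of the group, with exact Poisson 95% intervals. Ratios are log2 of (CPM + 1) in one group over (CPM + 1) in the other, and folds are on that scale. Each contrast used the active and silent cells, and was repeated within the 4 strata formed by the other factors (for day against night, these are active cFOS+, active cFOS-, silent cFOS+ and silent cFOS- cells). Shares of cells with a read were taken after thinning every cell to 4210000 reads, which left out 30 shallower cells, and have exact Clopper-Pearson 95% intervals.

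Before the data were examined, 27 gene lists, the rule for naming genes, the markers of cell types, the Vip class and most alternatives were fixed. A list member was measured with at least 5 CPM in one group. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Genes were named when they had at least 20 CPM in one group, a read in at least 10% of the cells of the higher group, and the same direction in the pooled value, the 4 strata, the mean over cells, the thinned share and the value without the top cell of each group. Predicted, ribosomal protein and mitochondrially encoded genes were left out of that choice. They were ranked by the smallest of the pooled, mean-over-cells and without-top-cell ratios, and the 12 highest and 12 lowest were taken; a few genes that these rules select are not reported here. Fos, Slc20a1, Slc20a2, Xpr1, Vip and Avp were given throughout, and each list described was illustrated by its 2 to 4 members with the largest ranking value at 20 CPM or more. Which lists to describe, and with how many examples, was chosen after the values were seen, as were Arntl and Per1.

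A Vip class was set at 100 CPM of Vip, with 10 and 1000 CPM as alternatives. The class, its comparison with other cells and the clusters used all cells, depolarized ones included, unless a firing label is given. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution of 1), and a cluster was named from the fixed markers when at least 3 markers of a single type were detected with 5 reads in at least 25% of its cells and were at least 2-fold higher than in other cells. The cluster that reached 3 markers of more than 1 type is described without a single name, a choice made after the data were seen, as were the cutoffs for a marker. The clustering settings were also chosen then: these were run first, a second method gave clusters with less clear markers, and the first was kept. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest. The other settings tried were the mean over cells, thinned counts, leaving out the top cell of each group or the 10% of cells with fewest genes, the authors' normalized signal, pseudocounts of 0.1 and 10, the mean of the strata, cells with numbers below or above the median number in the titles, and other detection limits. Leaving out cells with at least 100 CPM of summed microglia markers, leaving out S70 and S71, leaving out depolarized cells from the Vip class comparison, and a second clustering were added after the data were seen, and so was the limit of 100 CPM, for which 1000 CPM had also been considered. In simulated day and night cells with 200 changed genes among 8149, the median recovered log2 ratio was 0.96 for genes changed 2-fold and 1.90 for genes changed 4-fold. These folds were built into the simulated means, so the medians check the calculation and say nothing on the spread of single genes. A list of 31 genes raised 2-fold lay at percentile 100 and an unchanged list at percentile 38.4. Genes were simulated independently of each other, so this says nothing on the percentiles of lists whose members vary together across cells.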

Results

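The data are transcript counts of single SCN neurons whose firing was recorded before collection, with 3187057 to 25535298 reads per cell and a median of 6320667. By day there were 51 active cFOS+, 27 active cFOS-, 17 silent cFOS+ and 32 silent cFOS- cells, and by night 41, 46, 35 and 35. A further 14 cells were labelled depolarized (day: 2 cFOS+ and 7 cFOS-; night: 3 cFOS+ and 2 cFOS-). After a near-identical pair of night silent cells was counted as 1, the contrasts below held 127 day against 156 night cells, 143 cFOS+ against 139 cFOS- cells, and 165 active against 118 silent cells. Each group was 1 sample without replicates, so the differences are those between these collections of cells and were not tested.

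Clock genes differed between the day and night cells. Of 20 measured clock genes, 15 were higher by day, with a median log2 ratio of 0.37 (percentile 100 of 10000 random lists) and stratum medians from 0.29 to 0.91. Nr1d1, which encodes the repressor REV-ERB alpha (chromosome 11, 98767932 to 98775333, minus strand), stood at 782.5 CPM (95% interval 780.6 to 784.3) by day and 273.5 CPM (272.5 to 274.5) at night, a 2.86-fold difference that ran from 1.34 to 1.69 on the log2 scale across the strata. The clock output factor Dbp was 3.86-fold higher by day (a log2 ratio of 1.95), the repressor Ciart 4.17-fold (163.2 against 38.4 CPM) and Nr1d2 2.38-fold (183 against 76.3 CPM), each in all 4 strata. Among lower and higher cell numbers, the log2 ratio was 2.68 and 1.44 for Ciart and 0.60 and 1.95 for Nr1d2. In the opposite direction, Arntl, which encodes the activator BMAL1 (chromosome 7, 113207465 to 113314126), had 98.0 CPM by day and 232.7 CPM at night and was lower by day in all 4 strata. Per1 was at 84.5 CPM by day and 52.7 CPM at night. Arntl and Per1 were chosen after their values were seen.

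**Figure D1:**
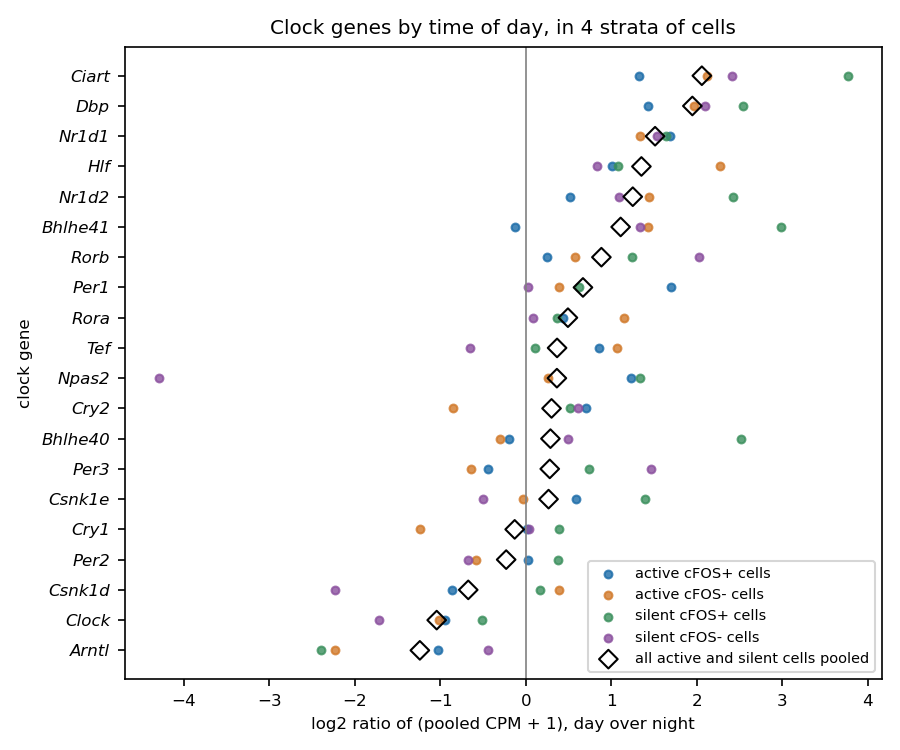
Log2 ratio of pooled CPM + 1, day over night, for the 20 measured clock genes; coloured points are the 4 strata of cells and open diamonds all active and silent cells pooled. Nr1d1, Dbp and Ciart lie to the right of 0 in every stratum and Arntl to the left, with pooled values of 1.51, 1.95, 2.06 and -1.24.

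Activity-induced immediate early genes were also higher by day. Of 31 measured members without Fos, 25 were higher by day, with a median log2 ratio of 0.47 (percentile 100) and stratum medians from 0.02 to 0.85. Junb, a subunit of the AP-1 transcription factor, was at 698.8 CPM by day and 371.6 CPM at night and was higher in all 4 strata. Fosl2 was 2.67-fold higher by day, in 3 of the 4 strata, with log2 ratios from 0.61 as the mean of the strata to 3.69 among higher cell numbers. Fos itself (chromosome 12, 85473890 to 85477273) was at 2714 CPM by day and 2014 CPM at night, a log2 ratio of 0.43, and higher by day in all 4 strata. Among signalling genes, 17 of 29 measured cAMP and calcium genes were higher by day (median 0.11). The G protein regulator Rgs16 was 4.32-fold and the phosphodiesterase Pde10a 3.26-fold higher by day, both in all strata, Gem was 1.95-fold higher in 3 strata (log2 0.36 among lower cell numbers), and the adenylyl cyclase Adcy2 was 1.90-fold lower in all strata. SCN transcription factors were higher by day for 9 of 14 members (median 0.29, percentile 98.3, stratum medians -0.31 to 0.37), led by Rorb at 289.6 against 156.4 CPM and Tshz2 at 59.0 against 36.8 CPM, although the log2 ratio of Tshz2 was 0.034 without the cells with microglia markers described below. Of 16 glutamate receptor subunits, 5 were higher by day (median -0.34, percentile 1.56). Grm7 and Grin2c had log2 ratios of -1.13 and -1.11, each lower in 3 strata, and Grin2c was at 0.67 among cells with lower and -3.08 among cells with higher cell numbers.

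The phosphate transporter Slc20a2 (PiT-2, a sodium-dependent importer; chromosome 8, 22476788 to 22569612, plus strand) was lower by day. Its pooled level was 44.4 CPM (44.0 to 44.9) by day and 90.2 CPM (89.6 to 90.8) at night, a 2.01-fold difference with the same direction in all 4 strata (log2 -2.60 to -0.63). The difference was smaller among lower cell numbers, with a log2 ratio of -0.36, than among higher ones, with -1.64. A thinned read was found in 31.6% of day cells (23.2 to 41.0%) and 45.7% of night cells (37.3 to 54.3%), and these intervals overlap. At least 5 thinned reads were found in 27.2% by day and 34.3% at night. The related importer Slc20a1 (chromosome 2, 129198764 to 129211616) had 165.9 CPM by day and 135.2 CPM at night, and the exporter Xpr1 (chromosome 1, 155275701 to 155417415) 84.6 and 105.2 CPM, with strata on both sides of 0 for each. Of 10 measured phosphate and inositol pyrophosphate genes, 4 were higher by day (median -0.30, percentile 1.53, stratum medians -0.28 to 0.16); without the cells with microglia markers described below, the percentile was 17.4. Among lower cell numbers 1 member of this list was higher by day. Ip6k2, an inositol hexakisphosphate kinase, was 1.51-fold lower by day in all strata.

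Among SCN neuropeptides, 8 of 17 were higher by day. Prok2, a secreted output signal of the SCN, was 5.33-fold higher by day, at 77.8 against 13.8 CPM, and higher in all strata. Avp (chromosome 2, 130580620 to 130582554) was at 3633 CPM by day and 1211 CPM at night, a log2 ratio of 1.58, and higher by day in all strata. Vip (chromosome 10, 5639218 to 5647617) was at 1790 CPM by day and 2972 CPM at night, and lower by day in all strata, with a log2 ratio of -0.73 pooled and -2.34 as the mean of the strata. Npy had 38.04 against 0.80 CPM but was higher by day in only 2 strata and at a log2 ratio of -0.25 among cells with lower cell numbers, and Trh was lower by day at 311.1 against 1032 CPM, higher in 1 stratum. Without the top cell of each group, the log2 ratio of Npy went from 4.44 to 1.78 and that of Trh from -1.73 to -3.56. The list median was -0.34 pooled (percentile 0.05), the mean over cells put it at percentile 77.4 and leaving out the top cell of each group at a median of 0.33, so no direction was read from it.

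Markers of microglia and astrocytes were higher in the day cells too. All 11 microglia markers were higher by day (median 1.72, percentile 100), among them P2ry12 at 87.5 against 13.4 CPM, Cx3cr1 at 52.5 against 9.18 CPM and Csf1r at 143.6 against 32.2 CPM. Without the cells with microglia markers, a set chosen by these same genes, their log2 ratios were 0.0044, 0.57 and 0.10, and among lower cell numbers that of P2ry12 was 0.13. Of 12 astrocyte markers, 10 were higher (median 1.37), led by Ntsr2 and Agt at 4.95 and 4.60-fold, and of 5 oligodendrocyte markers 4 were higher (median 0.96), with Olig1 and Mbp at 2.44 and 1.94-fold, each in 3 strata. With no limit on expression 6 of 12 oligodendrocyte markers were higher by day, so that list has no settled direction. The stratum medians ran from 0.22 to 3.13 for microglia, -0.23 to 1.09 for astrocyte and -5.49 to 2.22 for oligodendrocyte markers. At least 100 CPM of summed microglia markers was found in 43.3% of day cells (34.6 to 52.4%) and 32.7% of night cells (25.4 to 40.7%). Without these cells, 16 clock genes and 29 immediate early genes were higher by day, and 10 of the 11 microglia markers were higher with a median of 0.38. Mitochondrially encoded genes were higher by day for 8 of 9 members with these cells and for 2 of 9 without them, and Ntsr2 and Olig1 turned to log2 ratios of -0.20 and -1.54 and Agt was at 0.66.

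The 12 genes ranked highest by day were Cd9, Unc93b1, Eepd1, P2ry12, Rasl11b, Enox2, Shroom2, Fam159b, Prok2, Sox13, Evi2a and Tapbpl, with log2 ratios from 2.42 (Prok2) to 3.23 (Cd9); P2ry12 and Prok2 are also list members described above. Rasl11b was the most abundant of them at 258.5 against 40.5 CPM. Without the cells with microglia markers, Unc93b1, an endosomal trafficking protein of immune cells, turned to -1.34, and P2ry12 was at 0.0044 and Evi2a at 0.71. Genes ranked highest at night included Ift140, Sfmbt2, Alg6, Zfp790, Gramd4, Polr1b, Aph1b, Bcat2, Fam43a, Tmem132c and Vangl2, with log2 ratios from -3.05 (Aph1b) to -1.92 (Tmem132c), but Fam43a was at -0.20 and Gramd4 at -0.98 among lower cell numbers. Agreement of single genes between strata was near that of chance: 14.7% of 8637 genes at 20 CPM or more had the same sign in all 4 strata, where independent signs give 12.5%. Across genes, which are not independent replicates, the log2 ratios of separate strata correlated at Pearson r of 0.04 to 0.11 and Spearman rho of 0.03 to 0.07.

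The cFOS contrast asked how cells labelled positive for this activity marker differed from cells labelled negative. Fos was checked first and went against the label: it stood at 2005 CPM (2002 to 2008) in cells labelled cFOS+ and 2676 CPM (2672 to 2679) in cells labelled cFOS-, a log2 ratio of -0.42 that was negative in all 4 strata (-0.73 to -0.24) and stood at -0.82 among lower and -0.11 among higher cell numbers. A thinned Fos read was found in 92.9% of cFOS+ and 93.7% of cFOS- cells. The directions below therefore refer to the labels alone. Of 31 other immediate early genes, 9 were higher in cells labelled cFOS+ (median -0.35, below all 10000 random lists). Without cells with microglia markers 13 were higher, with a median of -0.11. The list median was 0.11 by day and -0.78 at night, so the lower level was that of the night cells. Ier2 was at 64.9 against 154.6 CPM (log2 -1.84 without cells with microglia markers) and Dusp6 at 25.4 against 45.2 CPM, each lower in 3 strata. Vgf, a secreted granule protein induced by activity, was 1.61-fold higher in cells labelled cFOS+ in all 4 strata.

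Cells labelled cFOS+ carried more Vip. Vip was at 3759 CPM (3755 to 3763) against 1139 CPM (1137 to 1142), 3.30-fold higher and higher in all strata (log2 0.45 to 4.12), with log2 ratios of 2.34 among lower and 0.85 among higher cell numbers. The share of cells with a read was 29.1% against 23.02%, intervals that overlap, or 25.98% against 14.3% with at least 5 reads, and cells with at least 100 CPM of Vip made up 24.5% (17.7 to 32.4%) against 12.2% (7.29 to 18.9%). Of 17 neuropeptides, 8 were higher (median -0.04), and without cells with microglia markers 11 were (median 1.09), so the list has no settled direction. Cartpt was 4.82-fold higher in cells labelled cFOS+ in all strata, but the share of cells with a thinned Cartpt read was 15.75% against 15.87%. Cck was 5.37-fold lower in all strata, at 18.5 against 103.6 CPM, with a log2 ratio of -1.55 among higher cell numbers. Gal had a log2 ratio of -1.64, lower in 3 strata, but 0.62 without cells with microglia markers. Avp was at 2711 against 1902 CPM. The receptors Avpr1a, Prokr2 and Vipr2 were lower in all strata, at 2.31, 2.17 and 1.93-fold, within a list of which 6 of 13 were higher (median -0.41, percentile 5.82); after thinning 2 of the 13 were. As the mean of the strata the log2 ratios of Avpr1a and Prokr2 were -3.04 and -2.74. Slc20a2 (72.3 against 67.8 CPM), Slc20a1 (140.4 against 159.2 CPM) and Xpr1 (97.5 against 95.6 CPM) had strata on both sides of 0.

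Of 26 genes of the secretory pathway, 19 were higher in cells labelled cFOS+ (median 0.15, percentile 98.2). The list median was 0.009 by day and 0.25 at night, but the median difference over its genes was -0.0077. No difference between day and night was therefore read from this list. Cadps2, which primes dense-core vesicles, was 1.68-fold higher and the prohormone convertase Pcsk1 2.01-fold higher in all strata, and Chga was 1.52-fold higher in 3. Over the other settings the log2 ratio of Cadps2 ran from 0.18 to 1.20. All 9 measured mitochondrially encoded genes were higher (median 0.38, percentile 99.9, stratum medians -0.34 to 0.79), with mt-Nd5 and mt-Nd6 at log2 ratios of 0.73 and 0.42. Nuclear oxidative phosphorylation genes were higher for 27 of 36 members (median 0.11, percentile 96.9), but their median was -0.07 by day and 0.19 at night. Ndufa4 was at 266.6 against 199.6 CPM and Ndufa1 at 138.3 against 105.6 CPM. Neuron markers were higher for 11 of 12 members (median 0.12). Gad2 and Gad1, which make GABA, were 1.53 and 1.34-fold higher, and Rbfox3 was 1.45-fold lower. Calcium and HCN channel genes were higher for 6 of 22 members (median -0.36, percentile 1.20), with Cacnb3 and Hcn3 at log2 ratios of -1.02 and -0.90, each lower in 3 strata, Hcn3 at 0.075 among cells with lower and Cacnb3 at -0.18 among cells with higher cell numbers. Microglia markers were higher for 1 of 11 members (median -0.46, percentile 0.37, stratum medians -2.47 to 0.40), with P2ry12 at 30.4 against 63.5 CPM (log2 -1.04, -1.71 without the top cells and -0.0040 without cells with microglia markers) and Aif1 at 23.9 against 50.8 CPM (log2 -0.43 after thinning). Over the other settings 0 to 5 microglia markers were higher, with 5 after thinning. At least 100 CPM of summed microglia markers was found in 31.5% of cells labelled cFOS+ and 43.9% of cells labelled cFOS-.

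By the ranking rule, the genes highest in cells labelled cFOS+ included Dclk3, Sod3, Emp1, Nos1, Suv39h1, Cmtm8, Gcfc2, Epn2, Peak1, Csgalnact2 and Vip, with log2 ratios from 1.72 (Vip) to 2.68 (Nos1, the neuronal nitric oxide synthase, at 35.95 against 4.76 CPM). Highest in cells labelled cFOS- were Vmac, Epha7, Tfb1m, Cdc25b, D10Wsu102e, Gria3, Cdh7, Osgin2, Cck, Skp2, Kat2b and Recql, with log2 ratios from -3.86 (Vmac) to -2.20 (Recql). Cdh7 was at -0.31 without cells with microglia markers and Epha7 at -1.07 among higher cell numbers. Gria3, an AMPA receptor subunit, was at 8.70 against 58.8 CPM, with reads in 15.8 and 40.5% of cells. The same sign in all 4 strata was held by 14.03% of 8624 genes, against 12.5% for independent signs.

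Firing was compared between active and silent neurons. Immediate early genes were higher in active cells for 24 of 31 members (median 0.34, percentile 99.99), and the medians of the strata ran from 0.13 to 0.54. Klf4 was 3.11-fold and the nuclear receptor Nr4a1 1.87-fold higher in all strata. The log2 ratio of Klf4 was 1.64, 2.80 without the top cell of each group, and 0.82 and 3.95 among lower and higher cell numbers. Btg2 and the synaptic scaffold gene Homer1 were 2.03 and 2.37-fold higher in 3 strata. Over the other settings the log2 ratio of Homer1 ran from 0.86 to 2.04, the highest among higher cell numbers. Fos was at 2479 CPM (2476 to 2482) in active and 2119 CPM (2116 to 2122) in silent cells, higher in all strata with log2 ratios of 0.07 to 0.39; among cells with lower cell numbers alone the pooled ratio was -0.091. Without cells with microglia markers, 23 of the 31 members were higher in active cells. Among clock genes 12 of 20 were higher (median 0.16, percentile 97.2), with Bhlhe40 at 90.2 against 49.0 CPM and Ciart at 115.4 against 65.2 CPM. Bhlhe40 was higher in 3 strata, with log2 ratios over the other settings from 0.39 to 1.49, the highest among lower cell numbers.

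Several peptides differed with firing. Sst was 4.24-fold higher in active cells (519.9 CPM in active cells), Vip 2.96-fold higher (3384 against 1142 CPM) and Pdyn 2.48-fold higher, while Avp was 2.04-fold lower (1599 against 3260 CPM), each in all 4 strata. Without the top cell of each group the log2 ratio of Sst went from 2.08 to 3.07, and it ran from 0.80 among lower to 7.85 among higher cell numbers. Vip was at a log2 ratio of 3.06 among cells with lower and -0.0092 among cells with higher cell numbers. Over the other settings Avp ran from -1.64, without cells with microglia markers, to -0.57. Cells with at least 100 CPM of Vip made up 23.6% of active cells (17.4 to 30.9%) and 11.0% of silent cells (5.998 to 18.1%). Of 17 neuropeptides 9 were higher (median 0.18, percentile 98.3; the mean over cells gave percentile 39.4). Phosphate and inositol pyrophosphate genes were higher in active cells for 9 of 11 members (median 0.23, percentile 95.2). Ppip5k2, an inositol pyrophosphate kinase, was at 60.4 against 28.96 CPM and Slc20a1 at 172.2 against 116.9 CPM, each higher in 3 strata. Slc20a2 was at 73.9 against 63.9 CPM and Xpr1 at 95.6 against 96.6 CPM, with strata on both sides of 0; Slc20a2 was at -0.15 among cells with higher cell numbers, and Xpr1 changed sign under several settings.

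Sodium, potassium, calcium and HCN channel genes showed no common direction with firing. Of 13 sodium channel genes 7 were higher in active cells (median 0.02), with Scn8a 1.55-fold lower in all strata and Scn9a 1.62-fold higher in 3. Over the other settings the log2 ratio of Scn8a ran from -1.28, among higher cell numbers, to -0.045, so its difference was not settled. Of 30 potassium channel genes 15 were higher (median -0.02), with the leak channel gene Kcnk3 2.16-fold higher in all strata. Of 22 calcium and HCN channel genes 12 were higher (median 0.06). The ryanodine receptor genes Ryr3 and Ryr2, which release stored calcium, were 3.57 and 2.19-fold higher in active cells in all strata. Without cells with microglia markers the log2 ratio of Ryr3 was 3.65 and that of Ryr2 0.16, and among higher cell numbers that of Ryr3 was 0.71. Glutamate receptor subunits were higher in active cells for 12 of 16 members (median 0.17, percentile 88.9), and among lower cell numbers for 8 of 16. GABA-A receptor subunits were higher in active cells for 4 of 11 members (median -0.25, percentile 4.86), with Gabrg3 at a log2 ratio of -0.66, lower in 3 strata. Nuclear oxidative phosphorylation genes were higher for 7 of 36 members (median -0.15, percentile 1.06), with Atp5l and Atp5e at log2 ratios of -0.53 and -0.50. Their median was 0.08 by day and -0.30 at night, so the lower level was that of the night cells. Without cells with microglia markers, 11 of the 36 were higher, and over all other settings 6 to 12.

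The genes ranked highest in active cells were Srd5a1, Zfp319, Cep95, Zfp82, Lysmd3, Dph2, Gdpd2, Pard6g, Npy1r, Sgms2, Sst and Abcc1, with log2 ratios from 2.05 (Abcc1) to 3.69 (Srd5a1, at 34.1 against 1.72 CPM). Dph2 was at 0.33 among higher and Zfp82 at 1.06 among lower cell numbers. Those highest in silent cells were Maob, Mfng, Zfp825, Irf9, Rxrg, Cwf19l1, Aff3, Rbms1, Map3k9, Il13ra1, Jmjd4 and Pla2g15, with log2 ratios from -3.56 (Mfng) to -2.07 (Jmjd4). Maob encodes a monoamine oxidase and was at 2.49 against 31.3 CPM. The same sign in all 4 strata was held by 14.4% of 8662 genes, against 12.5% for independent signs.

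**Figure D2:**
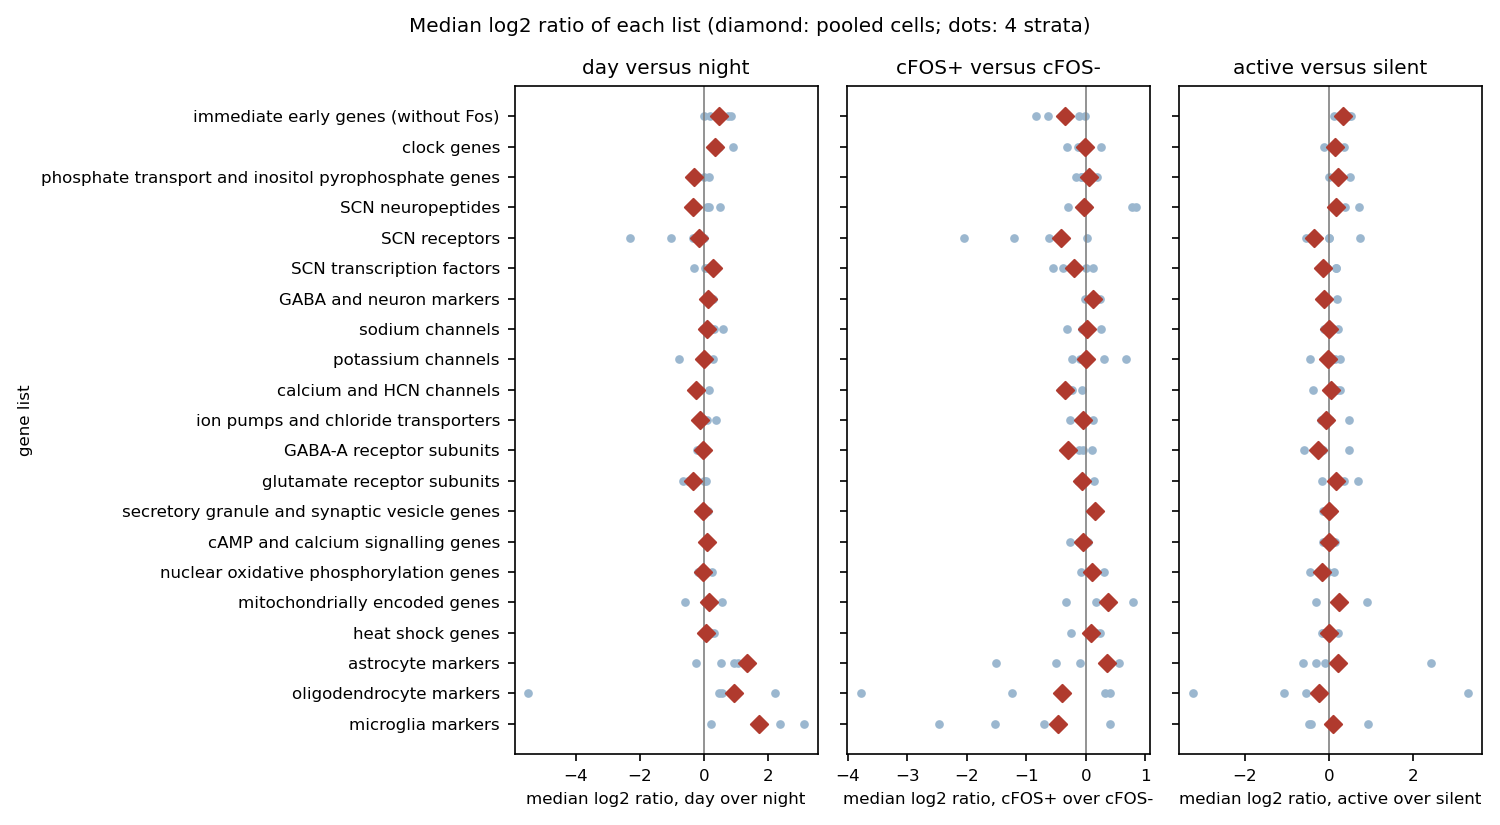
Median log2 ratio of each gene list in the 3 contrasts; diamonds are pooled cells and dots the 4 strata, with each panel on its own horizontal scale. Immediate early genes lie at 0.47 for day over night, -0.35 for cFOS+ over cFOS- and 0.34 for active over silent.

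The 14 depolarized cells were set against active cells of the same time and cFOS label. Slc20a2 was at 10.2 CPM in depolarized and 66.9 CPM in active cells, and in the day cFOS- cells alone, 7 against 27, at 3.36 and 48.3 CPM. Fos was at 2904 and 2665 CPM. Of 17 neuropeptides 5 were higher in depolarized cells, among the lower Sst at 25.7 against 946.7 CPM. Mitochondrially encoded genes were higher for 11 of 11 members (median 0.52), among them mt-Cytb at 2997 against 1788 CPM, and in the day cFOS- cells for 8 of 10. Microglia markers went in opposite directions, with 10 of 11 higher over all classes and 0 of 11 higher in the day cFOS- cells. Of 31 immediate early genes 20 were higher over all classes and 13 in the day cFOS- cells. These values rest on few cells.

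The factors were crossed, so each contrast was also read within the levels of the others, as differences of log2 ratios that were not tested. Immediate early genes had a day over night median of 0.85 in cFOS+ and 0.06 in cFOS- cells, with a median difference of 0.76. Microglia markers moved with them, with medians of 2.72 and 0.77 and a median difference of 1.95. The clock list was higher by day in both (0.67 and 0.22). Vip was lower by day by a log2 ratio of -0.42 in cFOS+ and -2.79 in cFOS- cells, and of -0.49 in active and -2.70 in silent cells. Slc20a2 was lower by day in active (-0.88) and silent (-1.27) cells and in cFOS+ (-1.24) and cFOS- (-0.79) cells. Avp was higher by day in active (1.12) and silent (2.00) cells.

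The series concerns a phosphate transporter in VIP neurons, so Slc20a2 was compared inside and outside a Vip class, the 55 of 297 cells with at least 100 CPM of Vip (18.5%, interval 14.3 to 23.4%). Only 2 cells lay within 2-fold of that limit. Slc20a2 was at 176.5 CPM (175.2 to 177.9) in the Vip class and 44.0 CPM (43.7 to 44.3) in all other cells, a log2 ratio of 1.98 (1.47 among lower and 2.67 among higher cell numbers). At least 5 thinned reads were found in 51.1% (36.1 to 65.9%) of Vip class cells and 25.9% (20.3 to 32.2%) of the others, and at least 1 in 53.2 and 35.0% (54.5 and 35.5% without thinning). The median cell had 1.03 CPM in the Vip class and 0 outside it. Slc20a1 was higher inside (interval 204.5 to 207.5 CPM) than outside (134.6 to 135.7 CPM), and Xpr1 was at 98.8 and 94.99 CPM.

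Within the Vip class, Slc20a2 lay between 68.7 and 71.4 CPM (95% interval) in 24 day cells and at 253.5 CPM (251.3 to 255.7) in 31 night cells, a log2 ratio of -1.84 that was -0.88 among lower and -3.23 among higher cell numbers and -3.90 without cells with microglia markers. These cells include 2 day and 1 night depolarized cells, all without a Slc20a2 read, and without depolarized cells the ratio was -1.81. Outside it the values were 36.8 and 50.2 CPM. At least 5 thinned reads were found in 38.1% (18.1 to 61.6%) of day and 61.5% (40.6 to 79.8%) of night Vip class cells, intervals that overlap. Cells are not replicates, so this difference in the share of cells was not tested. Among active Vip class cells the levels were 66.6 CPM in 20 day and 284.6 CPM in 19 night cells. Only 2 silent day cells were in the class, at 198.8 CPM, against 11 silent night cells at 232.9 CPM. Slc20a1 in the class was at 245.3 CPM by day and 177.5 CPM at night, and Xpr1 at 74.2 and 116.5 CPM.

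**Figure D3:**
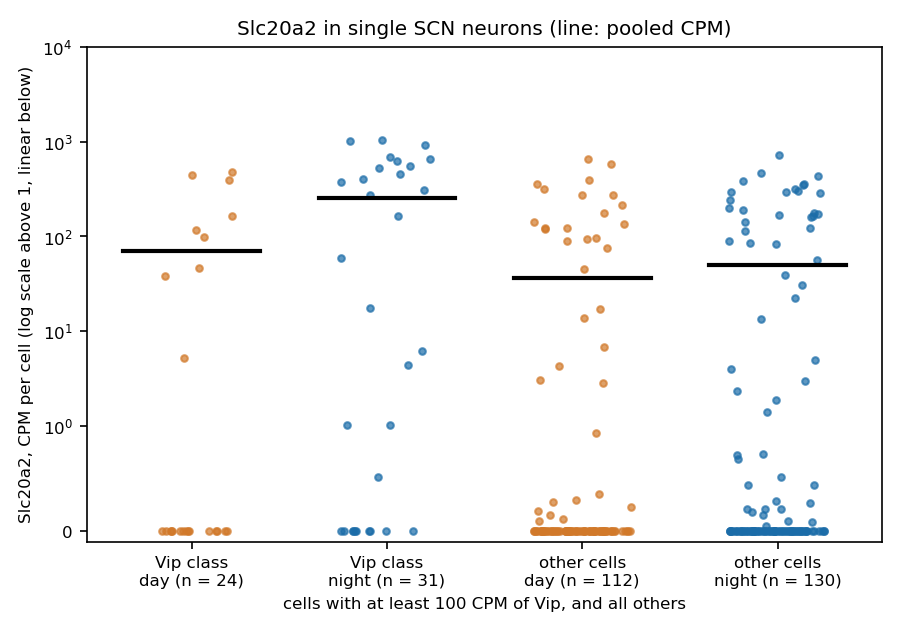
Slc20a2 CPM of each cell by time of day, for cells with at least 100 CPM of Vip and all others; points are single cells, lines the pooled CPM, and the vertical axis is logarithmic above 1 CPM and linear below. The pooled level of night Vip class cells is 253.5 CPM, above that of day Vip class cells (interval 68.7 to 71.4 CPM) and of the others (36.8 by day and 50.2 CPM at night), and cells without a read are present in all 4 groups.

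Clustering gave 7 clusters of 71, 52, 49, 44, 30, 28 and 23 cells. The cluster of 52 cells was AVP-like (Avp, Nms, Prok2 and Rgs16). It held 35 day and 17 night cells, and Avp, Prok2 and Rgs16 were higher in day cells, so it can follow time of day as well as cell type. The unnamed cluster of 49 cells also met Avp, with a median of 2415 CPM against 289.9 in the AVP-like cluster. The cluster of 23 cells met all 6 microglia markers, the astrocyte markers Gfap, Slc1a3 and Aldoc, and Mbp and Mobp of oligodendrocytes, so it was given no single name. It was led by Cd14, Il1a and Ccl9, and its cells also had a median of 702 CPM of the neuronal gene Gad1 and 1612 CPM of Snap25. The cluster of 28 cells, led by Chrm3, Glt8d2 and Fam19a1, met Vip and Grp and stayed unnamed, with 11464 CPM of Vip on average. It held 21 of the 55 Vip class cells, and the unnamed cluster of 44 cells, with Prokr2 among its leading genes, held 16. Of day Vip class cells 11 lay in the former and 4 in the latter, and of night cells 10 and 12. Among the markers met by the cluster of 71 cells were Sst and Slc17a6, the glutamate transporter of excitatory neurons.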

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

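The differences below were picked out because the same contrast ran in opposite directions, by a log2 ratio of at least 0.3 each way, at the levels of another factor. The limit of 0.3 was chosen after the differences had been seen. Each side was 1 group of cells and the differences were not tested. Xpr1 was lower by day in active cells (-0.84) and higher by day in silent cells (0.38), a difference of -1.22. Read the other way, Xpr1 was lower in active than silent cells by day (-0.73) and higher at night (0.49), which is the same difference of -1.22. The cFOS+ over cFOS- ratio of Slc20a2 was 0.32 among active and -0.32 among silent cells, a difference of 0.64. The SCN neuropeptide list had a day over night median of -0.50 in cells labelled cFOS+ and 0.46 in cells labelled cFOS-, with a median difference of -0.32 over its genes. List values are medians over members, and a median difference need not equal the difference of medians. Astrocyte markers had 12 measured genes, oligodendrocyte markers 5, and the other lists below 1 to 3. The glutamatergic list, with 1 measured gene in the day and cFOS contrasts, had a day over night ratio of -1.45 in cells labelled cFOS+ and 0.43 in cells labelled cFOS-, a difference of -1.88, which is also that of its cFOS contrast by day (-1.17) and night (0.71). Its cFOS contrast was -0.96 in active and 1.27 in silent cells, a difference of -2.23. Day over night, oligodendrocyte markers were at 1.502 in active and -0.49 in silent cells (median difference 1.80) and vascular markers at 0.33 and -0.52 (0.52). Over the cFOS labels, astrocyte markers were at 0.73 in active and -0.81 in silent cells (1.32), ependymal and tanycyte markers at 0.76 and -0.66 (1.43) and blood markers at 1.30 and -1.26 (2.41). Active over silent, these lists were at 1.40, 0.98 and 0.64 in cells labelled cFOS+ and -0.37, -0.32 and -1.76 in cells labelled cFOS-, with the same differences of 1.32, 1.43 and 2.41. Astrocyte markers, active over silent, were at 0.64 by day and -0.43 at night (1.34). In the 7 day depolarized cFOS- cells, the largest gap between an extreme cell and the rest was 0.55 of the range, for the percent of mitochondrially encoded reads, below Dixon's 95% critical value for that number of cells.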

How the results depend on the processing

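The values without the cells with microglia markers, those without S70 and S71, those without depolarized cells, and the second clustering were chosen after seeing the data. Clock genes higher by day ran from 14 to 16, microglia markers higher by day from 9 to 11, and immediate early genes higher by day from 18 to 29 and in active cells from 19 to 28. With members at 50 CPM or more, 5 immediate early genes were higher in cells labelled cFOS+, and fewer genes enter that count by construction. Microglia markers higher in cells labelled cFOS+ ran from 0 to 5, clock genes from 6 to 15 of 20, and microglia markers higher in active cells from 2 to 9. Nuclear oxidative phosphorylation genes higher by day ran from 12 to 23, the highest for lower cell numbers. Settings that change the expression limit alter how many genes enter. A pseudocount of 10 lowered the ratios of genes with few CPM in a group, for example Cd9 to 1.89, Vmac to -1.68 and Srd5a1 to 1.91. Without the top cell of each group, Alg6 was at -3.09 and Fam43a at -2.97 by day over night, Sod3 at 3.18, Skp2 at -3.08 and Kat2b at -2.21 for cFOS+ over cFOS-, and Srd5a1 at 4.56 for active over silent. The percent of cFOS+ cells with a Vip read was 40.7 for lower and 19.1 for higher cell numbers. With 5 reads required, the percent of cFOS- cells with Vip was 14.3 and of night cells with Slc20a2 34.3 (27.2 by day). The cause was not tested for any of the values that follow. The log2 ratio of Slc20a2 in the Vip class over other cells was 1.84 and 1.59 with the class at 10 and 1000 CPM, 1.87 thinned, 1.94 without the top cells, 1.89 without the cells with fewest genes, 2.10 with the authors' normalized values, 2.00 and 1.79 with pseudocounts of 0.1 and 10, 1.47 and 2.67 for lower and higher cell numbers, 1.80 without cells with microglia markers and 2.02 without depolarized cells. Its day over night ratio within the class was -1.97 and -2.17 with the class at 10 and 1000 CPM, -1.80 as the mean over cells, -1.91 thinned, -2.16 without the top cells, -2.06 without the cells with fewest genes, -1.79 with the authors' normalized values, -1.72 with a pseudocount of 10, -0.88 and -3.23 for lower and higher cell numbers, -3.90 without cells with microglia markers and -1.81 without depolarized cells. Of 138 alternatives of 13 list counts, shares of cells and Vip class ratios, 109 stayed within limits around the main value, and 6 results moved. Of 1874 alternative log2 ratios of 156 results, 25 reversed, in 14 results. Many of these could not reverse. A pseudocount keeps the sign, and genes named by the ranking rule were chosen for the same sign over cells, without top cells and in all strata. By day over night, without cells with microglia markers, Unc93b1 was -1.34, Ntsr2 -0.20 and Olig1 -1.54, and for lower cell numbers Npy was -0.25 and Grin2c 0.67. For cFOS+ over cFOS-, Slc20a1 was 0.088 as the mean over cells, 0.14 with normalized values and 0.071 for lower cell numbers. Slc20a2 was -0.34 as the mean of the strata, -0.021 for lower cell numbers and -0.064 without cells with microglia markers. Xpr1 was -0.23 as the mean over cells, -0.11 thinned, -0.0040 without the top cells, -0.19 with normalized values and -0.14 for higher cell numbers. Gal was 0.62 without cells with microglia markers and Hcn3 0.075 for lower cell numbers. For active over silent, Fos was -0.091 for lower cell numbers, Slc20a2 -0.15 and Vip -0.0092 for higher cell numbers. Xpr1 was 0.061 thinned, 0.083 without the cells with fewest genes, 0.072 for higher cell numbers and 0.39 without cells with microglia markers. A second clustering gave 6 clusters with an adjusted Rand index of 0.43, so cluster membership depends on the settings. The counting error of reads is small at this depth, but reads are not counted molecules. The CPM intervals therefore do not cover how many molecules were caught from each cell. The lack of replicates is a further limit. No paired analysis was possible because no label ties cells to an animal or slice.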

Other observations

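The tests of Fos and of immediate early genes without cells with microglia markers, of Fos at 100 CPM, and of Slc20a2 without its 3 highest cells were chosen after the result or a close relative of it was seen. Genes found together with Vip were counted at 100 CPM or more. Nms reached that level in 34 of the 55 Vip class cells (61.8%, interval 47.7 to 74.6%) and 32.2% of other cells (26.4 to 38.5%), and the calcium-binding protein gene Calb2 in 69.1% (55.2 to 80.9%) and 26.9% (21.4 to 32.9%). Grp reached it in 18.2% (9.08 to 30.9%) and 1.65% (0.45 to 4.18%), and Penk in 38.2 and 18.6%. Avp was at that level in 12.7% of Vip class cells (5.27 to 24.5%) and 39.3% of the others (33.1 to 45.7%). Sst and Cartpt were at that level in 0 of 55 Vip class cells (upper exact binomial limit 6.49%) and in 9.92 and 10.7% of other cells.

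The remaining lists had these counts. By day over night, members higher by day were 5 of 12 SCN receptors, 9 of 12 neuron markers, 7 of 12 sodium, 16 of 31 potassium and 7 of 22 calcium and HCN channel genes. They were 5 of 15 ion pumps and chloride transporters, 5 of 11 GABA-A receptor subunits, 12 of 26 secretory genes, 13 of 36 nuclear oxidative phosphorylation genes (23 for lower cell numbers and 20 without cells with microglia markers), 8 of 9 mitochondrially encoded genes and 7 of 10 heat shock genes. They were also 0 of 1 glutamatergic, 1 of 3 vascular, 2 of 3 ependymal and tanycyte, 0 of 2 blood and 2 of 4 sex-linked genes. With the same members, 3 SCN receptors were higher by day as the mean of the strata, 11 calcium and HCN channel genes with normalized values, 4 heat shock genes for lower cell numbers and 2 mitochondrially encoded genes for higher cell numbers. Vascular, ependymal and tanycyte and sex-linked genes reached 0 and blood genes 2 under other settings, so no direction was read from these lists. For cFOS+ over cFOS-, members higher were 9 of 20 clock, 7 of 10 phosphate, 6 of 15 SCN transcription factor, 8 of 13 sodium and 16 of 31 potassium channel, 5 of 15 ion pump, 4 of 11 GABA-A receptor, 6 of 16 glutamate receptor and 12 of 29 cAMP and calcium genes. They were also 6 of 10 heat shock, 7 of 12 astrocyte, 1 of 5 oligodendrocyte, 0 of 1 glutamatergic, 2 of 3 vascular, 2 of 3 ependymal and tanycyte, 1 of 3 blood and 1 of 4 sex-linked genes. With the same members, clock genes ran from 6 to 15, astrocyte markers were 4 without the top cells, and sodium channel genes 3 for lower cell numbers. For active over silent, members higher were 6 of 13 SCN receptors, 6 of 15 SCN transcription factors, 4 of 12 neuron markers, 7 of 15 ion pumps, 14 of 26 secretory, 15 of 29 cAMP and calcium, 9 of 10 mitochondrially encoded and 5 of 10 heat shock genes. They were also 9 of 12 astrocyte, 2 of 5 oligodendrocyte, 9 of 11 microglia, 0 of 2 glutamatergic, 0 of 3 vascular, 2 of 3 ependymal and tanycyte, 0 of 3 blood and 1 of 4 sex-linked genes. Here mitochondrially encoded genes were 2 for higher cell numbers, microglia markers 2 after thinning, and neuron markers 8 without cells with microglia markers. Cells with at least 100 CPM of microglia markers had neuron markers at a median log2 ratio of 0.06 for 12 genes, in 113 such cells over 184 others, from -0.74 (Slc32a1) to 1.62 (Nefl).

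A candidate explanation for the higher immediate early genes by day is RNA of microglia taken up with the neuron, which can carry the same genes. Without the cells with microglia markers 29 of the 31 genes were higher by day, with a median of 0.55, which argues against those cells as the main source. In the kept cells the microglia markers were still higher by day, with a median of 0.38, so remaining microglia RNA is not excluded. The removal was not repeated within the cFOS labels, where both lists moved together. A different share of Vip cells by day and by night was argued against by the cells outside the Vip class, where 28 of 31 were higher. Inside the class 21 were higher, exactly the limit set beforehand. Giving the cells outside it more weight was chosen only after both counts had been seen. The time of slice preparation differs with the label, so a response to slicing at different clock phases stays open and was not tested.

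Fos was not higher in cells labelled cFOS+. Whether Fos was already high in nearly every cell by the time of collection stays open. At least 100 CPM was found in 87.4% of cFOS+ and 84.2% of cFOS- cells, but nearly every cell was already known to hold a Fos read, so these shares decide nothing. RNA of microglia cannot be told apart from a difference in the neurons. Without the cells with microglia markers the log2 ratio was -0.23 instead of -0.42, between the limits set for and against, and it also ran from -0.82 to -0.11 between lower and higher cell numbers with those cells kept. Wrong labels were not tested, and how the label was given is not stated in the sources used here.

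The lower Slc20a2 of day Vip class cells might rest on a few cells or on different kinds of Vip cells. Without the 3 highest cells of each group the log2 ratio was -2.68. Without thinning, 37.5% of day and 67.7% of night Vip class cells had a read. This removal therefore takes a larger part of the day cells with a read, and whether a few cells carry the difference stays open. The ratio was -1.73 within the cluster with the most Vip cells (11 day and 10 night cells) and -2.02 among the other Vip class cells (13 and 21). Membership of that cluster therefore does not account for it alone. The other Vip class cells were themselves mixed, with 4 day and 12 night cells in the cluster of 44 and 6 and 4 in that of 52. Other kinds of Vip cells therefore stay open. Leaving out 1 top cell had been seen before the test without 3 was set up. A lower level by day in Vip neurons remains a hypothesis. Differences between animals or slices stay open, since no label names them, and the biological explanation, time of day itself, cannot be separated from them here.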
